A study of Mus musculus with 4 samples.

How the data were processed

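Total RNA of 4 pools of small intestinal tumours (3 tumours per pool) was labelled with biotin and hybridised to Illumina mouse bead arrays, 1 array per pool. The groups were small tumours (at most 2 mm) and large tumours (4 to 5 mm), with 1 pool of each size from each of 2 ApcMin/+ mice, so a group held 2 arrays. The 2 pools with the same mouse number came from the same animal, per the labels. Without the mouse as a block, the p-values of probes therefore rest on the spread between 2 animals, each seen through a pool of 3 tumours. A spread pooled over probes enters them too. The gene list p-values with a preset correlation compare genes with genes, and do not measure the spread between animals.

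The scanner table gave for each of 45281 probes a bead signal, its standard error over beads, the number of beads and a detection p-value. The signals were linear intensity values exported by the authors with no normalization and no background subtraction, per the file headers, which name the gene expression module version 3.2.6; BeadStudio is named in the submitters' processing notes. The deposited detection p-value of a probe compares its signal with the array's negative control probes, which were not listed in the table. The authors also deposited a matrix of normalized linear intensity values for 15274 probes; how it was made is not given in the sources used here. Every probe in it had a detection p under 0.05 on all 4 arrays, a limit that 16072 probes met and of which it left out 798. Its values lay a median of 3.06% from a quantile normalization of the uncorrected signals, and the 15274 rows of the series value table matched its rows to 4 decimals. An example sheet of the submission template held other column names and was not used. No per-sample column of the scanner table was left unmapped.

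Median signals were 59.1 and 63.0 for the small pools of mouse 1 and mouse 2, and 61.4 and 60.2 for the large pools. The median signal of detected probes was 3.21 to 3.74 times that of undetected ones, and the median standard error over beads was 5.05% to 5.92% of the signal. For arrays, the number of arrays limits the precision.

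Signals were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3: normexp background correction with the background taken from the detection p-values, an offset of 16, quantile normalization between arrays and log2. A first run took log2 before the quantile step; it was replaced by neqc itself, which the design names, after its results had been seen, and its values are kept as an alternative. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were tested (20214 probes). Gene symbols were those of the files, updated through RefSeq gene names of the assembly GRCm38.p6: 27740 probes had a current symbol, 8037 an older one that was updated, and 9504 kept the name in the file. The files name no genome build, and no coordinates are given. A gene was represented by its tested probe with the highest mean (13906 genes). Where a probe was not well above background on both arrays of a group, the fold is a bound: the mean of the brighter group against, per array, the higher of the lowest log2 value among detected probes and the probe's own. A difference within a mouse or between the mice with 1 such array is given as a bound in the same way; the tests, counts, ranks and list medians used the normalized values.

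Large were compared with small tumours with lmFit and eBayes of limma (two-sided, Benjamini-Hochberg adjusted p under 0.05), without the mouse as a block. The fit with the mouse as a block was an alternative, and its value, or its range over a group of genes, stands beside the genes named by size where it changes the call; for gene lists the number of members that passed with it is given. As a check of the pairing, the difference between the mice in small pools correlated with that in large pools across genes (Pearson r = 0.251); the pairing itself comes from the labels. Genes at least 2-fold apart in the same direction in both mice were counted with no test. Gene lists with at least 5 tested genes, 37 in number, were tested with camera of limma (preset correlation 0.01), and camera with an estimated correlation, fry and the percentile among 10000 random lists matched on mean expression were computed beside it. With the preset correlation, camera takes its degrees of freedom from the number of genes. With an estimated one it uses the residual degrees of freedom, 2 without the block and 1 with it. Few lists could be called on so few, so a list not called that way decides little. The lists covered gastric mucous and Brunner gland genes, proximal and distal small intestine, epithelial cell types, Wnt targets and stem cells, immune cells and cytokines, stroma, vessels, muscle and nerve, pancreas, blood and fat, and cell processes from proliferation to housekeeping.

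The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule named Tff1, Tff2 and Tff3; in each direction 12 genes, first those past the test with the same sign in both mice by mean difference, then genes of the same sign detected on both arrays of the brighter group, ranked by the smaller of the differences in the 2 mice; and up to 4 members per list with the largest mean difference. Since no gene passed, all 12 places per direction went to the second kind. Predicted, clone and accession names kept their places and were not described (3 of the 12 higher and 5 of the 12 lower).

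The scripts were tested on simulated data for the comparison of large with small tumours (20214 probes, 200 of them changed, 20 data sets for each of 2 models of the spread between pools). The first model drew residual variances from the blocked fit, and the second drew total variances from the unblocked fit. Without the block, the share of changed probes recovered under the first model was 2.46% at a log2 difference of 1, 69.6% at 2 and 99.6% at 3, and under the second 0.149%, 16.8% and 82.2%; 2.48% and 2.24% of its calls were false. With the block the recovered shares were 12.6%, 92.5% and 100% under the first model and 1.42%, 44.6% and 92.1% under the second. The blocked fit did not hold its error rate: 15.7% and 12.01% of its calls were false, and its prior degrees of freedom, estimated from 1 residual degree of freedom per probe, varied between data sets (from 13.4 to infinite under the first model, and from 4.57 to 11.2 under the second). Its calls are therefore given as a second reading of the data. In the data its prior degrees of freedom were 12.8, between the ranges of the 2 models. Without the block they were 5.03, within the range of the second model (4.55 to 5.20). The first model gave 11.0 to 21.3, so its recovered shares without the block come from a spread unlike that of the data. In the same simulations, on 5000 probes, camera found a list of 20 probes shifted by 1 log2 unit in all 20 data sets of both models. The simulated probes varied independently of each other. In the data the estimated correlation between genes of a list reached 0.74 (fibroblast and matrix), and false calls under such correlation were not simulated.

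The alternatives were no background correction, an offset of 50, cyclic loess, median scaling, the authors' normalized values, no filter, a strict filter (detection p under 0.01 on all 4 arrays), the mouse as a block, eBayes with trend and robust, leaving out each array, a 1.5-fold limit, the mean of a gene's probes, an estimated correlation and fry. A fit without 1 array compares unequal mixes of the 2 mice, so the difference between the mice enters its values and calls. Combinations of the mouse block with these settings, each mouse alone, and the order of log2 and quantile were added after seeing the data. The adjustment over a list alone was not among the fixed alternatives. It makes no correction over the 37 lists, and with the block it keeps that fit's raised share of false calls. The mouse as a random block could not be fitted, since duplicateCorrelation gave no correlation for any of the 20214 probes on 4 arrays, and the slide as a block was not run, since the files name no slide. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.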

Results

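Total RNA from small intestinal tumours of 2 ApcMin/+ mice was measured on Illumina bead arrays. ApcMin/+ mice carry a truncating mutation in 1 copy of Apc, a negative regulator of Wnt signalling, and develop many intestinal adenomas. The animals were 30 weeks old and of the C57BL/6J strain. From each mouse, 3 small tumours of at most 2 mm and 3 large tumours of 4 to 5 mm were pooled separately, which gave 4 arrays: small and large in mouse 1, and small and large in mouse 2. The title of the study names trefoil factor family 2 (Tff2), so the comparison of large with small tumours asks which transcripts, Tff2 among them, differ with tumour size. Between 18969 and 19990 of 45281 probes were detected per array. The number of arrays, 2 per size, limits the precision of every value below, and an exact permutation test of 2 against 2 cannot go below p = 0.333 (two-sided).

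Tff2, a secreted peptide of gastric mucous cells and of the Brunner glands of the duodenum, was 10.5-fold higher in large than in small tumours. Its normalized log2 intensity was 9.11 ± 0.62 (SD, n = 2) in small and 12.49 ± 1.10 (SD, n = 2) in large tumours. The log2 difference was 3.05 in mouse 1 and 3.72 in mouse 2. Several other genes known from stomach mucosa went the same way in both mice; a difference against an array on which the probe was not detected is marked as a bound. The log2 difference of Pgc, the pepsinogen progastricsin, was 2.75 in mouse 1 and 3.30 in mouse 2, and that of the water channel Aqp5 was 2.31 and 3.18. Cldn18, a tight junction protein of the stomach, differed by 2.01 (a bound) and 1.79, and over both mice by 2.05 (1.24 with no background correction). The difference of the gastrokine Gkn3 was 1.13 in mouse 1 and 4.21 in mouse 2. Tff3, the trefoil factor of goblet cells, did not follow: its difference was -0.40 in mouse 1 and 0.89 in mouse 2. Tff1 was not among the probes tested.

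Tff2 did not pass the limma test over all 20214 probes without the mouse as a block (adjusted p = 0.516, higher in 2 of 2 mice), and it passed with the mouse as a block (limma adjusted p = 0.000687). Over all alternatives, with and without the block, the limma adjusted p of Tff2 ran from 1.06e-13 to 0.862, the highest with the block and no pooling of the spread over probes, and its log2 difference from 2.61 to 4.16. Without the small pool of mouse 1 or of mouse 2 the unblocked log2 difference was 2.94 or 3.83. Without the large pool of mouse 1 or of mouse 2 it was 4.16 or 2.61. Of the 21 tested genes on the list of trefoil and gastric mucous genes, 12 were higher and 2 were lower in both mice. With the mouse block 4 of them passed, all higher (Tff2, Aqp5, Cldn18 and Gkn3), and 17 did not pass. Adjusted over the list alone, 5 passed without the block (those 4 and Ctse, which encodes cathepsin E). With the block, 9 higher genes and 1 lower gene passed when adjusted over the list alone. The list as a set was higher in limma's camera test (adjusted p = 7.24e-06; adjusted p = 0.642 with an estimated correlation). Its median log2 difference was 0.15 in mouse 1 and 1.68 in mouse 2. Over the other background, normalization and filter settings the mouse 1 median ran from -0.25 (authors' values) to 0.99 (strict filter). The mouse 2 median ran from 0.89 (strict filter) to 1.87 (authors' values). These 2 settings hold 11 of the 21 genes. Gkn1 and Gkn2, named after their values were seen, went opposite ways in the mice: Gkn1 differed by -0.85 in mouse 1 and 3.37 in mouse 2, and Gkn2 by -1.72 and 5.36.

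**Figure D1:**
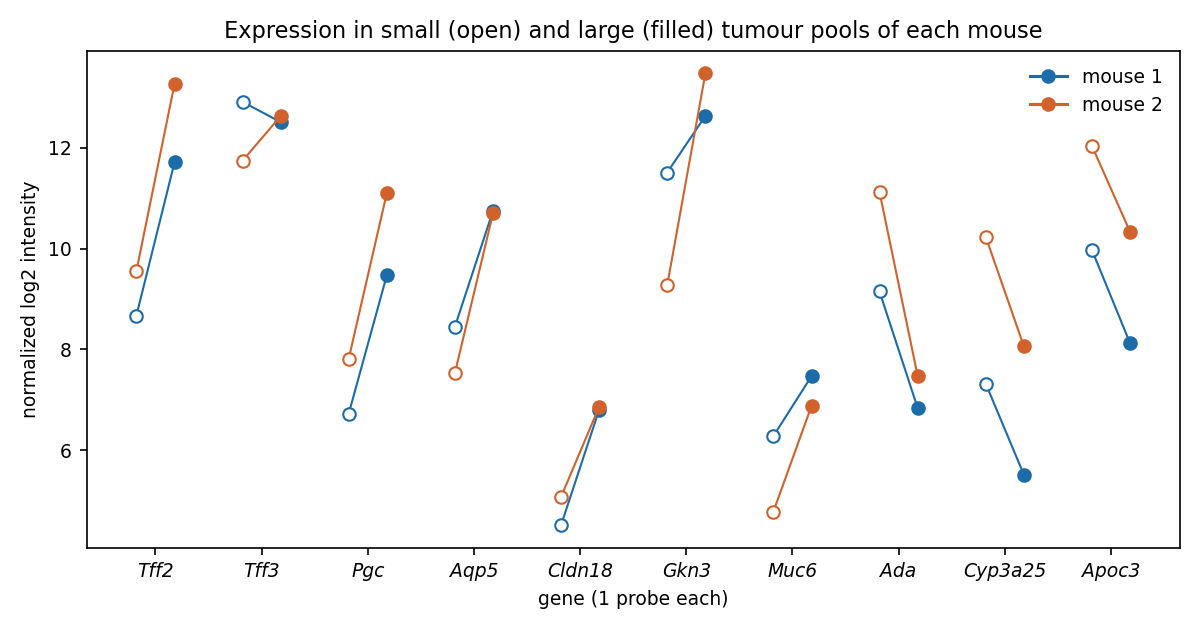
Normalized log2 intensity (vertical axis) of 10 genes on each of the 4 arrays; open points are small and filled points large tumour pools, and a line joins the pools of 1 mouse; probes not detected on an array are drawn at their normalized value. Tff2 lay 3.05 and 3.72 log2 units higher in the large pools of mouse 1 and mouse 2, Ada lay lower by more than 2 units in both mice, and Tff3 went -0.40 in mouse 1 and 0.89 in mouse 2.

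Over all genes, 131 of 13906 were at least 2-fold higher and 111 at least 2-fold lower in large tumours in both mice, and 29 were at least 2-fold apart in opposite directions. If the lists of the 2 mice were independent, 46.2 genes would be expected in the same direction, against 242 found, and 49.99 in opposite directions, against 29. This count had no test. For comparison, 251 genes differed at least 2-fold between the mice in both sizes, and 200 did in the crossed pairing of large with small pools. The 242 became 126 with no background correction, 128 with an offset of 50 and 115 with the authors' values, which hold fewer probes. Among the 12 places for higher genes were probes annotated to the major urinary protein genes Mup2 (3.55 in mouse 1 and 3.47 (a bound) in mouse 2, log2) and Mup1 (2.53 (a bound) and 2.12 (a bound)). The genes of this family are near-identical and the files hold no probe sequences, so these values could not be assigned to 1 member. The chitinase gene Chit1 was not well above background in small tumours and at least 6.72-fold higher in large ones (limma adjusted p = 0.160 without and 0.00231 with the mouse block). The calpain gene Capn6 differed by 2.38 and 3.11 (a bound), the pentraxin gene Nptx2 by 2.01 and 2.90, and F13a1, the A subunit of coagulation factor XIII, by 2.00 and 2.58. The probes of Mup2, Mup1, Pgc, Capn6, Nptx2 and F13a1 did not pass limma without the mouse block (adjusted p of 0.286 to 0.597) and passed with it (adjusted p of 0.000596 to 0.0141). Some of these sizes depended on the background correction: the log2 difference over both mice of Chit1 was 2.86 as reported, 1.85 with no correction and 1.89 with an offset of 50, so its bound holds only for the reported correction. With no correction that of Mup2 went from 3.74 to 2.75, of Mup1 from 2.56 to 1.59 and of Capn6 from 3.00 to 2.27.

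Among the genes lower in large tumours, Ada, the adenosine deaminase of proximal enterocytes, had a log2 difference of -2.32 in mouse 1 and -3.66 in mouse 2. The aldo-keto reductase gene Akr1b7 differed by -1.94 and -2.15, and the guanine deaminase gene Gda by -1.71 and -1.97. The cytochrome P450 gene Cyp3a25 differed by -1.81 and -2.18, and Apoc3, an apolipoprotein of lipid-absorbing cells, by -1.85 and -1.71. Ky differed by -1.84 and -1.47 (a bound). The chemokine gene Cxcl9, an interferon gamma target, had differences of -1.68 and -1.85. Of 36 tested probes for immunoglobulin variable segments, 33 were lower and 0 higher in both mice, with a median log2 difference of -1.24. With the mouse block 11 of them passed, all lower. This group was chosen after its values were seen. The 7 genes named before it did not pass limma without the mouse block (adjusted p of 0.516 to 0.682) and passed with it (adjusted p of 0.00389 to 0.0366). With no background correction the log2 difference over both mice of Ky went from -1.92 to -1.16 and that of Gda from -1.84 to -1.17.

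No probe passed limma without the mouse as a block: the smallest adjusted p was 0.0918, and 1563 probes had an unadjusted p under 0.05 against 1011 expected by chance. The same count was 1110 for mouse 2 against mouse 1 and 210 for the crossed split. With the mouse as a block, 120 probes passed, 68 higher and 52 lower, from 111 genes. For comparison, 155 passed for mouse 2 against mouse 1 with size as the block. With large and small exchanged in mouse 2 and the mouse as a block, 0 passed. The fit with the mouse as a block had 1 residual degree of freedom, and its calls rested on the spread pooled over probes. In simulated data of this design 15.7% and 12.01% of its calls were false under 2 models of the spread, against a set rate of 0.05. Neither model gave the prior degrees of freedom found in the data (12.8), so these shares are a guide only. Without pooling, no probe passed (smallest adjusted p = 0.217). With the block, none passed with no background correction, an offset of 50 or no filter. More were lower than higher with median scaling (173 higher, 284 lower) and with the strict filter (220 higher, 257 lower). With 1 array left out, the unblocked count rose without a large pool but not without a small one. The lone pool of a size was then assumed to vary like the others.

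**Figure D2:**
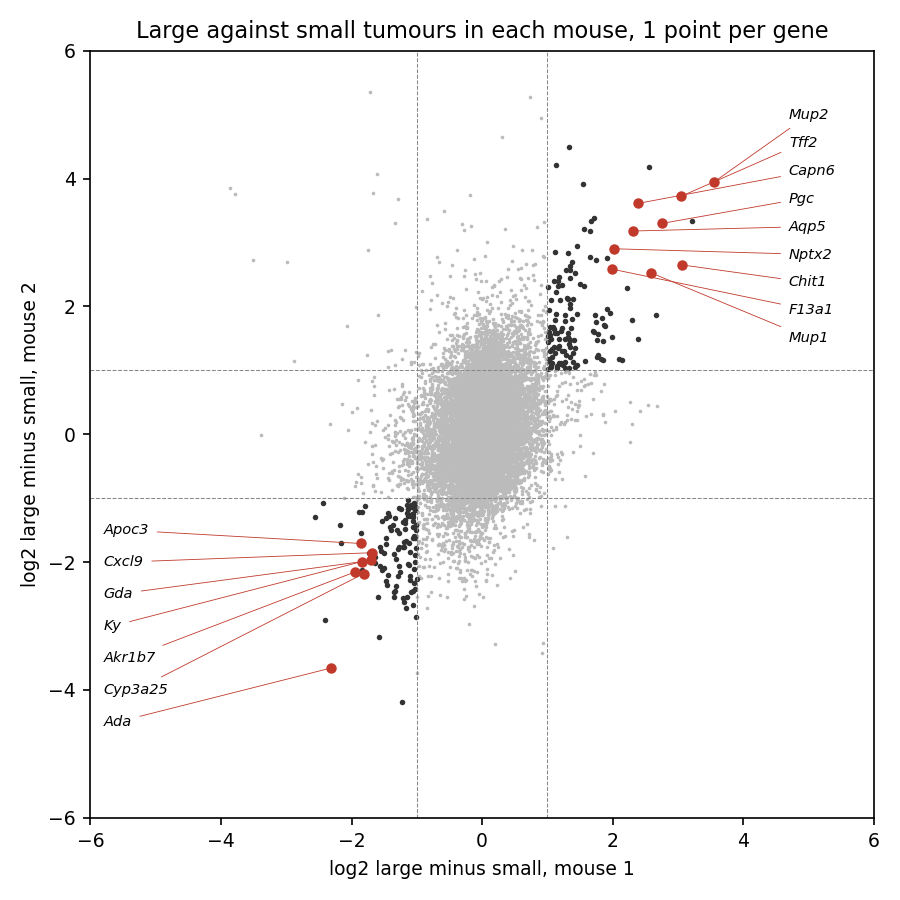
Log2 difference of large minus small tumours in mouse 1 (horizontal axis) and mouse 2 (vertical axis), 1 point per gene; dashed lines mark 2-fold, black points are at least 2-fold in the same direction in both mice, and red points are the named genes. Of 13906 genes, 131 lie in the upper right and 111 in the lower left corner, and the spread is wider in mouse 2 (SD 0.759) than in mouse 1 (SD 0.464).

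Genes of absorptive enterocytes were lower in large tumours. Of 33 tested, 28 were lower in both mice and 0 were higher in both, with a median log2 difference of -1.004 in mouse 1 and -1.01 in mouse 2. For comparison, 26.7% of all genes were lower and 30.7% higher in both mice. With the mouse block 4 members passed (Ada, Cyp3a11, Cyp3a25 and Apoc3) and 29 did not; adjusted over the list alone, 18 passed with the block and 4 without it. The list was called lower by camera (adjusted p = 2.46e-11; adjusted p = 0.642 with an estimated correlation). The small pool of mouse 2 stood apart from the other arrays (Pearson r across genes of 0.940 to 0.952 with them, against 0.963 to 0.978 among the others, genes not being independent replicates). The difference of Cyp3a11 was -0.82 (a bound) in mouse 1 and -4.19 in mouse 2. Without the small pool of mouse 2 it was 0.04, but that fit compares both large pools with the small pool of mouse 1. In large pools Cyp3a11 lay 2.12 (a bound) higher in mouse 2, which enters that value. Markers of the proximal small intestine were called lower too (camera adjusted p = 0.0338, and 0.796 with an estimated correlation). Of 13 tested, 7 were lower in both mice, and 2, Pdx1 and Gata4, were higher in both. Markers of the distal small intestine were also called lower (camera adjusted p = 0.0113, and 0.756 with an estimated correlation). Of 14 tested, 7 were lower and 1 was higher in both mice. The proximal call was lost without the small pool of mouse 2 (median 0.26), without the large pool of mouse 1 and with no filter (camera adjusted p = 0.105). The distal call was lost without the small pool of mouse 1 (median 0.29) and the large pool of mouse 2. A fit without 1 pool sets unequal mixes of the mice against each other, and these lists differed between the mice. In small and large pools, proximal genes lay 1.39 and 1.54 higher in mouse 2, and distal genes differed by -1.36 and -0.55. Within mouse 1 and mouse 2 the median was -0.61 and -0.70 for proximal genes, and -0.90 and -0.04 for distal genes. With the block 3 proximal and 0 distal genes passed. Among distal members, Muc3 differed by -1.03 in mouse 1 and -1.13 in mouse 2, whereas Fabp6, the ileal bile acid binding protein gene, differed by -0.69 and 2.77.

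Targets of Wnt signalling were higher as a set: 18 of 28 were higher and 2 lower in both mice, with medians of 0.49 and 0.89 (camera adjusted p = 8.07e-07; adjusted p = 0.642 with an estimated correlation). The differences of the Wnt antagonist gene Wif1 were 1.77 in mouse 1 and 1.24 in mouse 2, those of Nkd1 0.93 and 1.78, and those of Notum 0.90 and 1.55. Lgr5, a stem cell marker, differed by 2.03 and 0.37. No member passed over all probes with the block; adjusted over the list alone 9 passed with the block and 1 (Wif1) without it. On the list of intestinal stem cell genes 10 of 18 were higher in both mice, which was not called (camera adjusted p = 0.0688), and Olfm4 was lower (-0.36 and -1.60).

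Immune cell genes moved in both directions. Neutrophil genes were higher as a set (11 of 17 in both mice; camera adjusted p = 0.000237; adjusted p = 0.642 with an estimated correlation). The calgranulin gene S100a8 differed by 1.72 in mouse 1 and 3.38 in mouse 2, S100a9 by 1.67 and 3.34, and Retnlg by 1.39 and 2.12; these 3 passed with the block, and adjusted over the list alone 5 genes passed without it. Interferon response genes were lower (23 of 27 in both mice; camera adjusted p = 1.33e-08; adjusted p = 0.642 with an estimated correlation), with log2 differences of -1.02 and -1.89 for the GTPase gene Igtp and -1.20 and -1.68 for the peptide transporter gene Tap2. No interferon member passed over all probes, and adjusted over the list alone 2 passed without the block (Gbp3 and Tap2). T and NK cell genes (13 of 22 lower in both mice; camera adjusted p = 0.000350; adjusted p = 0.642 with an estimated correlation) and B and plasma cell genes (9 of 16; camera adjusted p = 0.0138; adjusted p = 0.642 with an estimated correlation) were called lower. Cd3e, a subunit of the T cell receptor complex, differed by -1.18 and -1.34, and Cd74, the invariant chain of antigen presentation, by -0.84 and -0.66; Prf1, which encodes perforin, was higher (0.81 and 1.40). Both calls were lost without the small pool of mouse 1 (adjusted p = 0.127 and 0.196), and the B cell call also without the large pool of mouse 1 (0.0987). Mast cell and eosinophil genes were called higher (6 of 12 in both mice; camera adjusted p = 0.0154; adjusted p = 0.756 with an estimated correlation), for example the carboxypeptidase gene Cpa3 (1.18 and 1.34 (a bound)). That call was lost without the small pool of mouse 2 (adjusted p = 0.545), with the authors' values (0.264), with no filter (0.0623) and with the strict filter (0.0897).

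Stromal genes were higher as sets. Of 34 fibroblast and matrix genes, 29 were higher and 0 lower in both mice (camera adjusted p = 2.24e-06; adjusted p = 0.782 with an estimated correlation), among them Timp1, an inhibitor of matrix proteases (1.42 in mouse 1 and 2.52 in mouse 2), the proteoglycan gene Lum (1.72 and 1.61) and Mgp (1.70 and 1.62). These 3 passed over all probes with the block, and adjusted over the list alone 9 did with it and 0 without it. Matrix proteases and their inhibitors (13 of 24 higher in both mice; camera adjusted p = 0.00110; adjusted p = 0.642 with an estimated correlation) included the serine protease inhibitor gene Serpine2 (2.00 and 1.52; limma adjusted p = 0.569 without and 0.0382 with the mouse block). Endothelial genes (12 of 24; camera adjusted p = 0.00658; adjusted p = 0.642 with an estimated correlation) included Cdh5, which encodes the junction protein VE-cadherin (0.68 and 1.49). Ribosomal protein genes, a list fixed as a check of labelling and RNA quality, were also called, and were higher in both mice in 30 of 40 (camera adjusted p = 0.000931; adjusted p = 0.796 with an estimated correlation), with a median of 0.07 in mouse 1 and 0.54 in mouse 2. Without the small pool of mouse 2, the array that stood apart, the calls of the 3 stromal lists and of the ribosomal list were lost (adjusted p = 0.0857 for fibroblast, 0.187 for protease, 0.0857 for endothelial and 0.210 for ribosomal genes). The fibroblast and endothelial calls were also lost without the large pool of mouse 1 (0.403 and 0.0987).

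Of the 37 lists, 14 were called (8 higher and 6 lower) and 23 were not. With the mouse as a block, camera called the same 14 and 5 more, all higher: Brunner gland (median 0.20, adjusted p = 0.0741 without and 0.0360 with the block), inflammatory cytokine (median 0.32, adjusted p = 0.0583 without and 0.0149 with the block), enteric neural and glial (median 0.34, adjusted p = 0.0688 without and 0.0129 with the block), exocrine pancreas (median 0.51, adjusted p = 0.0583 without and 0.0315 with the block), Notch, BMP and TGF-beta (median 0.21, adjusted p = 0.0727 without and 0.0377 with the block). With an estimated correlation camera called none of the lists (smallest adjusted p = 0.642, and 0.732 with the block). That test had 2 residual degrees of freedom, and 1 with the block, so few lists could be called whatever their correlation. The Wnt list, for example, had an estimated correlation of -0.02, under the preset 0.01. Most called lists lay above the preset, such as enterocyte (0.51), ribosomal protein (0.62) and fibroblast and matrix (0.74). By these estimates the p-values of such lists with the preset correlation are too small. Fry, which tests whether a set's genes move on balance 1 way, called none (smallest adjusted p = 0.126). The uncalled lists had these median log2 differences: 0.27 for intestinal stem cell, 0.04 for regenerative and fetal, -0.07 for Paneth cell, 0.27 for goblet cell, -0.06 for enteroendocrine, 0.03 for tuft cell, -0.10 for proliferation, -0.34 for epithelial antimicrobial, 0.19 for macrophage and dendritic cell, 0.12 for smooth muscle, 0.28 for erythroid, 0.14 for adipocyte, -0.13 for hypoxia and glycolysis, -0.22 for immediate early and stress, 0.07 for epithelial-mesenchymal transition, -0.15 for cholesterol synthesis, 0.09 for oxidative phosphorylation, 0.02 for housekeeping genes; their camera adjusted p ran from 0.0583 to 0.801. Paneth cell, enteroendocrine and housekeeping lists had a median and a mean or test of opposite sign. Of the lists not called, 16 were called in at least 1 alternative with the preset correlation. Macrophage and dendritic cell genes were the only ones called in both directions: their median was -0.29 in mouse 1 and 0.72 in mouse 2, and camera called them higher without the small pool of mouse 1 (adjusted p = 0.000697) and lower without that of mouse 2 (adjusted p = 0.00143). Proliferation genes had a median of 0.22 in mouse 1 and -0.39 in mouse 2, and 5 of 32 were higher and 1 lower in both.

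**Figure D3:**
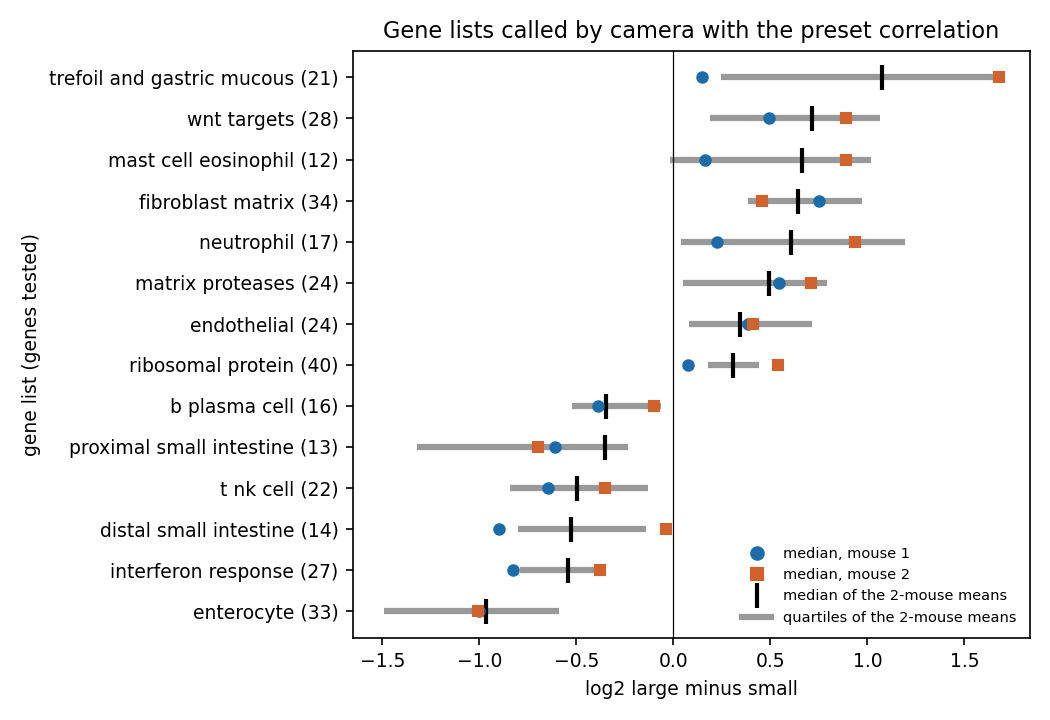
Median log2 difference of large minus small tumours (horizontal axis) for the 14 called gene lists, with circles for mouse 1, squares for mouse 2, a black bar for the median of the 2-mouse means and a grey bar for its quartiles; numbers in parentheses are genes tested. The enterocyte list lies lowest in both mice (medians -1.004 and -1.01) and by the 2-mouse means. The trefoil and gastric list lies highest by the 2-mouse means (median 1.07) and in mouse 2 (1.68). In mouse 1 (0.15) it lies below other lists, such as fibroblast and matrix (0.75).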

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

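The alternatives with the mouse block combined with another setting, each mouse alone, the order of log2 and quantile and the fit with no pooling of the spread were chosen after seeing the data. The count of probes past the test was 0 without the mouse block, and stayed 0 with no background correction, an offset of 50, cyclic loess, the authors' values, no filter and log2 before the quantile step. It was 2 with median scaling, 2 with the strict filter and 2 with trend and robust, and ran from 0 to 70 when 1 array was left out; the lone pool of a size was then assumed to vary like the others. The replicate block gave 120 probes (68 higher, 52 lower). Combined with it, cyclic loess gave 197, median scaling 457 (173 higher, 284 lower), the authors' values 36 (23 higher, 13 lower), the strict filter 477 (220 higher, 257 lower), log2 before the quantile step 113 and trend and robust 101, while no background correction, an offset of 50, no filter and no pooling gave 0. These counts went with the estimated prior degrees of freedom of the blocked fit, which were 2.09 with no filter, 4.26 with an offset of 50, 9.13 with the authors' values, 12.8 as reported, 17.0 with loess, 148 with the strict filter and infinite with median scaling. All 120 blocked probes were also called with loess and with median scaling, and of the 92 that the authors' values hold, 36 were. A blocked fit without 1 array leaves no residual degrees of freedom, so none was made. The log2 difference of Tff2 kept its sign in every setting run. Among fits on all 4 arrays, Tff2 passed only with the block. It did so at 3.39 with the replicate block as such and at 3.41 with loess. It also did at 3.38 with median scaling, 3.31 with the authors' values and 3.39 with the strict filter, log2 first or trend. Leaving out 1 array gave 2.61 to 4.16. Genes 2-fold in both mice numbered 242, against 126 with no background correction, 128 with an offset of 50, 115 with the authors' values, 912 at 1.5-fold, and 603 to 2218 in 1 mouse alone. The split of higher and lower genes changed with single mice: 256 and 347 in mouse 1, 1399 and 819 in mouse 2. The number of lists called was 14, and 0 with an estimated correlation, 0 with fry and 0 with the replicate block and an estimated correlation; in the other settings it ran from 11 to 21. The lists of gastric, Wnt, enterocyte, neutrophil and interferon genes were called in all 15 other settings that kept the preset correlation. The mouse as a random block gave no value, and the slide as a block was not run. Leaving out 1 array at a time turned the sign of these log2 differences, given as the range over the 4 fits: the proximal list (median) -1.48 to 0.26, the distal list (median) -1.13 to 0.29, Gpx5 -2.87 to 2.86, Fgf15 -3.41 to 1.23, Gpx6 -2.18 to 1.40, Saa1 -4.41 to 2.77, Atp4a -0.74 to 1.03, Tff3 -0.34 to 0.83, Vip -0.14 to 3.13, Fabp6 -3.29 to 5.37, Cyp3a11 -5.45 to 0.0371, Apoa4 -2.95 to 0.31, Reg1 -2.33 to 0.42, Lipf -1.10 to 3.56, Adh1 -3.20 to 1.90, Pnliprp1 -0.0859 to 2.63, Gkn1 -0.40 to 2.92, Gkn2 -0.97 to 4.60, Cblif -0.0489 to 2.57. Gpx5 also turned to 0.108 with loess and 0.0269 with median scaling, with or without the block. A fit without 1 array sets unequal mixes of the mice against each other, so a difference between the mice enters its value. Apoa4, for example, differed by -1.34 in mouse 1 and -1.31 in mouse 2. It lay 3.23 higher in mouse 2 in small pools and 3.26 in large pools. Why each of these values moved was not tested further. Signal over background limits the dim probes: 18969 to 19990 probes per array were detected.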

Other observations

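Genes of position along the small intestine differed between the mice in both sizes. Proximal genes had a median log2 difference of mouse 2 minus mouse 1 of 1.39 in small and 1.54 in large pools, and distal genes of -1.36 and -0.55. The enterocyte list, which shares genes such as Ada, Apoa4, Apoc3 and Cyp3a11 with the proximal one, had medians of 0.89 and 0.81, so the proximal difference cannot be read as position alone. Fabp6, an ileal gene, differed by -8.66 and -5.19, and the serum amyloid gene Saa1 by -6.98 (a bound) and -4.85. The alcohol dehydrogenase gene Adh1 (5.10 and 4.59), the apolipoprotein gene Apoa4 (3.23 and 3.26) and the trehalase gene Treh (2.75 and 2.51) were higher in mouse 2 in both sizes. These genes were chosen after the values were seen. The labels do not say from which part of the small intestine each pool came.

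Some genes went opposite ways in the mice by large amounts, and were chosen by the size of their normalized differences after the values were seen. Gpx5, a glutathione peroxidase gene of the epididymis, differed between large and small pools by -3.86 in mouse 1 and 3.49 (a bound) in mouse 2, and its neighbour in family Gpx6 by -3.09 (a bound) and 2.20 (a bound). Lipf, the gastric lipase gene, differed by -1.62 and 4.07. Of 13 tested genes of the exocrine pancreas, 6 were higher and 2 lower in both mice. Cela1 (0.80 and 2.41), Clps (0.79 and 1.21) and Pnliprp1 (0.69 and 1.85), named by the list rule, were higher, and Reg1 (-0.58 and -1.33), chosen after its values were seen, was lower. Of the epithelial antimicrobial list, the oxidase gene Nox1 was lower (-0.997 in mouse 1 and -3.73 in mouse 2) and the acute phase gene Saa3 was higher (0.84 and 3.24), both named by the list rule. Pdx1, a transcription factor gene of the duodenum and stomach antrum chosen after its values were seen, was 0.08 (a bound) and 1.58 higher. The ribosomal protein list, fixed as a check of labelling and RNA quality, had medians of 0.07 and 0.54 and was called higher, and whether RNA quality differed between the pools was not tested.

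All tests in the next 2 paragraphs were chosen after the pattern was seen, and the bounds of all but the stomach test after the result it measures. The first pattern is that Tff2 and other gastric mucous genes were higher in large tumours; the median of the list over both mice was 1.07, but 0.66 with no background correction and 0.69 with an offset of 50. Background correction or normalization as the whole cause is argued against for Tff2, whose lowest difference in a mouse over those settings and the authors' values was 2.94, and for the list in mouse 2, whose lower quartile stayed at or above 0.43; for the rest of the list in mouse 1 it cannot be told apart, since the lower quartile was already -0.24 as reported and -0.60 in the authors' values, which hold 11 of its 21 genes. Stomach body tissue in the large pools cannot be told apart, although both bounds set before were met. Of 8 stomach body genes, 37.5% were detected on both large arrays, under 50%, and the upper quartile of their log2 difference was 0.02, under 1. However, 4 of the 8 were detected on no array. Carried-over tissue would raise such genes from background, but no stomach sample shows that their probes respond to it. The exact 95% interval of the detected share (8.52% to 75.5%), which was not part of the bounds set before, holds 50%. Atp4a of acid-secreting cells differed by 0.24 and 0.05. Pgc (2.75 and 3.30) goes with such tissue in both mice. Lipf (-1.62 and 4.07) and Cblif (0.18, its small pool not detected, and 2.33) go with it in mouse 2 only. More Brunner gland tissue cannot be told apart either. The 9 Brunner gland genes off the gastric list had a median of 0.0207 and an upper quartile of 0.20, over members that went both ways. The bound for arguing against this cause needed members not detected on the small arrays. There were 0 of them, so the test could not have argued against it. Egf, detected on 2 small and 0 large arrays, and Nr5a2 (-0.42 and -0.47) were not higher but lie near background. Muc6 of both lists was higher (1.19 and 2.05 (a bound)), and no Brunner gland sample gives the levels that a share would bring. A difference with tumour size within the tumour cells stays open and untested. Staining sections of both sizes for Tff2 would show which cells hold the protein, but would not measure its RNA.

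The second pattern is that enterocyte genes were lower in large tumours. Background correction and normalization are argued against, since the highest upper quartile of the list in a mouse over the same settings was -0.37, below 0. Less adjoining normal mucosa in the large pools cannot be told apart from it: the goblet, Paneth and enteroendocrine genes, which that mucosa also holds, had a median of 0.0136 with quartiles of -0.16 and 0.46, over members that went both ways. Pools from another stretch of the intestine cannot be told apart either, as the highest of the proximal and distal list medians in a mouse was -0.0405, and these lists share absorptive genes with the enterocyte list. A difference with tumour size within the tumour cells stays open and untested. Staining sections of both sizes for an enterocyte protein would show which cells hold it. It would not show from which stretch of the intestine a tumour came.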
